A study of Mus musculus with 24 samples.

How the data were processed

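Bulk RNA sequencing was done on polyA RNA from memory B cells (csMBC in the labels) sorted from mice that received house dust mite extract through the nose and were given the same allergen again 6 weeks later. RNA came from a Zymo microprep kit, and libraries from an xGen broad-range kit adapted for few cells. The 24 libraries fall into 6 groups of 4: 3 sorted populations (lung CCR6+CD69+, lung CCR6-CD69- and circulating) from WT mice and from mice labelled SCAP cKO. The labels give 2 batches, and every group has 2 libraries in each. The labels name lung as the source of all libraries, the circulating ones included. Nothing in the labels says whether replicates were separate animals, so the p-values measure only the spread between these samples.

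The authors deposited whole-number counts per gene symbol, in 18470 rows and with 1 column per sample. The submitters' processing notes name FastQC, STAR, Salmon and genome build mm39 without versions, roles or settings, so it is not known which tool made the counts. Rows for several genes of interest are not analysed here, among them Ccr6, Sqle, Idi1, Fasn, Ighg1 and Prdm1. Total counts are therefore totals over the rows analysed. They ran from 129025 to 8566243 per library, and the limit set by 3 counts from 0.350 to 23.3 CPM (counts scaled to 1e6 per library); such limits cover counting error only.

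Differential expression was tested in R 4.3.3 with edgeR 4.0.16: trimmed mean of M values (TMM) scaling, the filterByExpr filter by group (6779 genes kept), and a robust quasi-likelihood F-test. All 24 libraries entered a single fit with terms for group and batch. P-values were adjusted by Benjamini and Hochberg's method over the genes tested in each comparison, with 0.05 as the threshold. Log2 fold changes are given with standard errors (SE). The common dispersion was 1.20, a biological coefficient of variation of 1.10. The 8 planned comparisons were the 3 population pairs in WT, the genotype effect in each population, and the difference of the genotype effect between lung CCR6+CD69+ and each other population. These, the gene lists, the rule for named genes and the first set of alternative settings were set before the data were examined.

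Of 34 gene lists covering sterol and lipid metabolism, B cell programmes and markers of other cell types, 31 had at least 4 tested members. Of 685 genes on the lists, 405 had a row analysed here and 353 were tested. A list result therefore covers its tested members only. They were tested on log2 CPM (prior count 2) with camera in limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. Adjustment was over the lists within each comparison. List scores are the mean log2 CPM of the tested members in a library. Scores were compared by two-sided exact permutation tests, which with 4 against 4 libraries cannot go below 0.0286.

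Genes were named by a fixed rule: Scap and the sorting marker Cd69, 4 SREBP targets (Hmgcs1, Insig1, Scd2 and 1 not reported here), and, among genes past the threshold with at least 5 CPM in the higher group, the 8 largest rises and the 8 largest falls. Up to 4 members with the smallest p were added for each list past the threshold. Other list members appear as examples.

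That first set was edgeR with relative log expression factors, DESeq2 1.42.0, no filter and a stricter filter (5 CPM in 4 libraries), immunoglobulin genes left out, no batch term, each batch alone, only the groups compared, a fold change minimum of 1 on the log2 scale, the replicate number as a block (13 genes in the first comparison), and each library left out in turn. Alternatives added after seeing the data left out the 2 libraries under 500000 counts, left out the 2 libraries in which Chil3 took most counts of any gene, or used limma voom with sample quality weights. The 3 population comparisons in SCAP cKO and the genotype effect averaged over populations were also added after seeing the data, as were marker lists of natural killer, plasmacytoid dendritic and T cells, written after the called genes and values per library were known.

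The test was tested on simulated data made from these libraries. With 100 genes changed 4-fold, 13% were called between the WT lung populations, 23% between WT lung CCR6+CD69+ and circulating, and 12% between genotypes in lung CCR6+CD69+. With 100 genes changed 16-fold these were 72%, 71% and 72%. Of 92, 102 and 89 genes called, 3, 5 and 2 had not been changed. A list of 12 raised genes was called in each, and 0 of 30 random lists. Simulated genes were drawn independently of each other, so this does not check lists whose genes move together. The changed genes and lists came from the more highly expressed of the tested genes, so these shares do not hold for all genes tested.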

Results

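Gene expression was measured in 24 libraries of sorted mouse memory B cells: lung CCR6+CD69+, lung CCR6-CD69- and circulating cells from WT and SCAP cKO mice, with 4 replicates in each of the 6 groups. SCAP escorts SREBP transcription factors, which switch on sterol and fatty acid synthesis, and in the cKO mice it was deleted before the allergen was given again. Total counts ran from 2765735 to 8566243 in WT lung CCR6+CD69+ libraries, 680077 to 3378171 in WT lung CCR6-CD69- and 356782 to 2466421 in WT circulating (n = 4 each). In the cKO groups, in the same order, they ran from 2081557 to 4181963, 129025 to 4641148 and 957610 to 2092658. The smallest libraries were cKO lung CCR6-CD69- replicate 4 (129025 counts, 2134 genes detected) and WT circulating replicate 2 (356782 counts). Replicates correlated across genes at 0.822 to 0.909 (Pearson's r of log2 CPM) in WT lung CCR6+CD69+ and at 0.425 to 0.694 in cKO lung CCR6-CD69-. Genes are not independent replicates in such a correlation. The batches differed in 530 genes (56 higher and 474 lower in batch 2, adjusted p under the threshold in edgeR), and ribosomal protein genes took 8.52 to 14.2% of counts in batch 1 and 2.51 to 3.59% in batch 2.

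**Figure D1:**
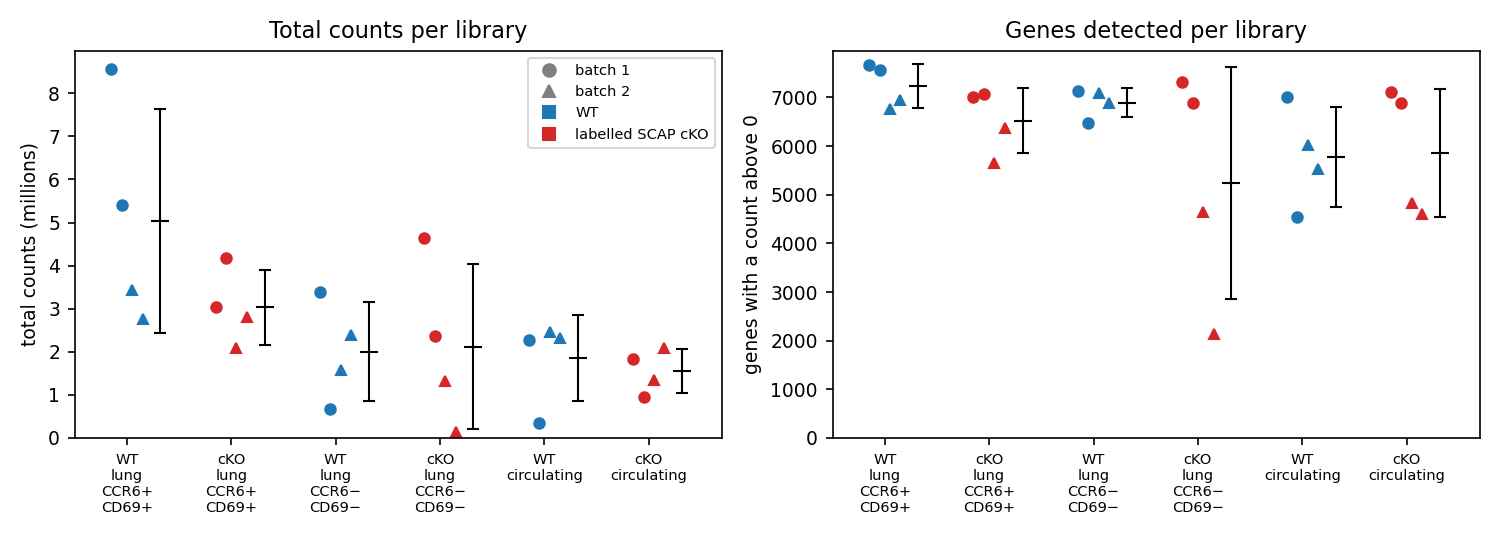
Total counts (left) and genes with a count above 0 (right) for each library, by group, with blue for WT, red for labelled SCAP cKO, circles for batch 1 and triangles for batch 2. Bars give the mean ± SD of 4 libraries, and the lowest point in both panels is cKO lung CCR6-CD69- replicate 4, with 129025 counts and 2134 genes.

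Scap, the gene deleted in the cKO mice, was counted at 81.0 ± 27.0 CPM in WT lung CCR6+CD69+, 141 ± 39.1 in WT lung CCR6-CD69- and 99.4 ± 71.8 in WT circulating libraries (SD, n = 4). In the libraries labelled SCAP cKO it was counted at 87.7 ± 61.0, 98.9 ± 78.7 and 246 ± 113 CPM. Its log2 fold change between genotypes was 0.08 ± 0.93 (SE), -0.54 ± 0.94 and 1.26 ± 0.95, with adjusted p of 1.00, 0.999 and 0.673 in edgeR. These counts cover the whole gene, so a deletion of some exons would not have to lower them. Cd69, a sorting marker that retains lymphocytes in tissue, was counted at 939 ± 201 CPM in WT lung CCR6+CD69+, 787 ± 127 in WT lung CCR6-CD69- and 622 ± 431 in WT circulating libraries. Though cells were sorted on the CD69 protein, the transcript did not pass between lung CCR6+CD69+ and lung CCR6-CD69- (log2 fold change 0.24 ± 0.55, adjusted p 1.000) or circulating libraries (log2 fold change 0.59 ± 0.56, adjusted p 0.901). Ccr6 was not analysed here.

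The first comparison asked how lung CCR6+CD69+ memory B cells differ from lung CCR6-CD69- cells in WT mice. Jchain, the joining chain of secreted IgM and IgA, averaged 190.0 ± 87.1 CPM in CCR6+CD69+ and 2432 ± 1774 CPM in CCR6-CD69- libraries (SD, n = 4), and fell in CCR6+CD69+ (edgeR, log2 fold change -3.67 ± 0.62, adjusted p 0.00275). The 8 largest falls included Dll4, a Notch ligand (-5.85 ± 1.20, adjusted p 0.0117), Ccnd1, the cyclin D1 of cell cycle entry (-4.27 ± 0.96, adjusted p 0.0221), and Lifr, the receptor for leukaemia inhibitory factor (-4.42 ± 1.05, adjusted p 0.0392). The phosphatase Ptprf (-6.48 ± 1.37), Tbc1d8 (-6.37 ± 1.22), the C-type lectin Clec10a (-6.04 ± 1.45), Fmnl2 (-5.84 ± 1.32) and Serinc5 (-3.91 ± 0.85) made up the rest, with adjusted p between 0.0170 and 0.0392. No gene passed as higher in CCR6+CD69+ in edgeR with the count filter and all libraries, while edgeR without the filter called 2, DESeq2 3 and limma voom 26 as higher.

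Among the gene lists, 8 of 9 tested plasma cell genes were lower in CCR6+CD69+ (camera adjusted p 5.42e-04; adjusted p = 0.0528 with an estimated correlation). Jchain fell, and 1 gene passed adjusted over the list alone; Sdc1, the plasma cell surface marker syndecan 1, had a log2 fold change of -4.37 ± 1.75 and did not pass. Of the unfolded protein response list, which holds chaperones of the endoplasmic reticulum, 11 of 12 members were lower (median log2 fold change -0.94, adjusted p 2.14e-04; adjusted p = 0.179 with an estimated correlation). None passed over all genes and 1 passed adjusted over the list alone, with Hsp90b1 at -1.08 ± 0.36, Manf at -1.26, Pdia6 at -0.84 and Hspa5 at -0.79. The recirculation and egress list had 8 of 12 members lower (median -0.90, also with Lef1, which had 0 counts in CCR6-CD69-, at its bound; adjusted p 0.0204, and adjusted p = 0.179 with an estimated correlation). In it 1 gene passed adjusted over the list alone, while S1pr1, the receptor that guides exit from tissue, was at -1.90 and Foxp1 at -1.45 without passing. The LXR target list was lower in 3 of 4 members (adjusted p 0.0118; adjusted p = 0.0870 with an estimated correlation): Pltp, a phospholipid transfer protein, fell (-3.81 ± 0.91, adjusted p 0.0392, 1 gene adjusted over the list alone), and Abca1, the cholesterol exporter, was at 0.31. The tissue residency list was not called (7 genes, adjusted p 0.760), nor were B cell identity (adjusted p 0.720) and cholesterol synthesis (adjusted p 0.336). The SREBP targets Hmgcs1 (-0.74 ± 0.89), Insig1 (-1.18 ± 0.81) and Scd2 (-1.04 ± 0.63) did not pass.

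Markers of other cell types differed between the same libraries. Whether RNA of such cells gave part of the falls above, those of Jchain and of the gene lists included, was not tested. All 17 tested macrophage and monocyte markers were lower in CCR6+CD69+ (median -2.20, adjusted p 4.73e-09; adjusted p = 0.179 with an estimated correlation), 0 of them past the threshold alone or adjusted over the list alone. They took 4.35% of counts in WT lung CCR6-CD69- replicate 2, where Chil3, a chitinase-like protein of lung macrophages, reached 25379 CPM, and at most 0.664% in the other 3 libraries of that group. T cell and NK cell markers were lower in 12 of 13 (adjusted p 0.0195; adjusted p = 0.394 with an estimated correlation; 1 adjusted over the list alone), with Cd4 at -3.34 ± 1.00. Dendritic cell markers were lower in 5 of 8 (adjusted p 0.00215; adjusted p = 0.0870 with an estimated correlation), where Clec10a fell and 2 genes fell adjusted over the list alone. Granulocyte markers went the other way, higher in 6 of 6 (median 3.12, adjusted p 7.42e-05; adjusted p = 0.0870 with an estimated correlation), with Mmp9 at 4.54 ± 2.07, S100a9 at 3.06 and 0 passing adjusted over the list alone. Of 22 tested plasmacytoid dendritic cell markers, on a list written after the values were seen, 19 were lower in CCR6+CD69+ (median -2.23) and 5 passed, Lifr and Pltp among them. Ccr9 averaged 6.64 ± 9.80 CPM in CCR6+CD69+ and 265 ± 112 CPM in CCR6-CD69- libraries without passing.

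By edgeR, 20 of 6779 genes passed (0 higher and 20 lower), with 226 at an unadjusted p under 0.05. DESeq2 called 54 and limma voom 155. The edgeR count was 38 with no filter and 81 with only the groups compared. The edgeR count was 28 without the 2 libraries under 500000 counts and 22 without the 2 led by Chil3. It was 6 in batch 1 alone and 2 in batch 2 alone, and 6 without a batch term. Leaving out WT lung CCR6+CD69+ replicates 1, 2, 3 or 4 gave 0, 6, 4 and 1 genes, and leaving out WT lung CCR6-CD69- replicates 1 or 3 gave 9 each.

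The comparison of lung CCR6+CD69+ with circulating memory B cells in WT mice asked which transcripts set the lung population apart from cells in circulation. Egr2, a transcription factor induced by antigen receptor signalling, averaged 838 ± 180.2 CPM in lung CCR6+CD69+ and 67.9 ± 41.4 CPM in circulating libraries (SD, n = 4) and rose in the lung (edgeR, log2 fold change 3.74 ± 0.65, adjusted p 1.93e-04). Among the other large rises were Bcl2a1b, a BCL2-family survival gene (5.02 ± 1.17, adjusted p 0.00990), Rasgrp3, a Ras activator downstream of the B cell receptor (2.98 ± 0.72, adjusted p 0.0181), and Abca1 (2.10 ± 0.57, adjusted p 0.0405). Nrp2 (5.22 ± 1.35), Tbc1d9 (4.71 ± 1.08), Trim5 (4.69 ± 1.17) and Scai (2.60 ± 0.65) also rose, with adjusted p from 0.00841 to 0.0263. Jchain fell (-3.02 ± 0.60, adjusted p 0.00201). The B cell gene Ms4a1 averaged 1303 ± 97.4 CPM in lung CCR6+CD69+ and 531 ± 218 CPM in circulating libraries. Whether RNA of other cells in the circulating libraries gave part of these rises and of the fall of Jchain was not tested.

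**Figure D2:**
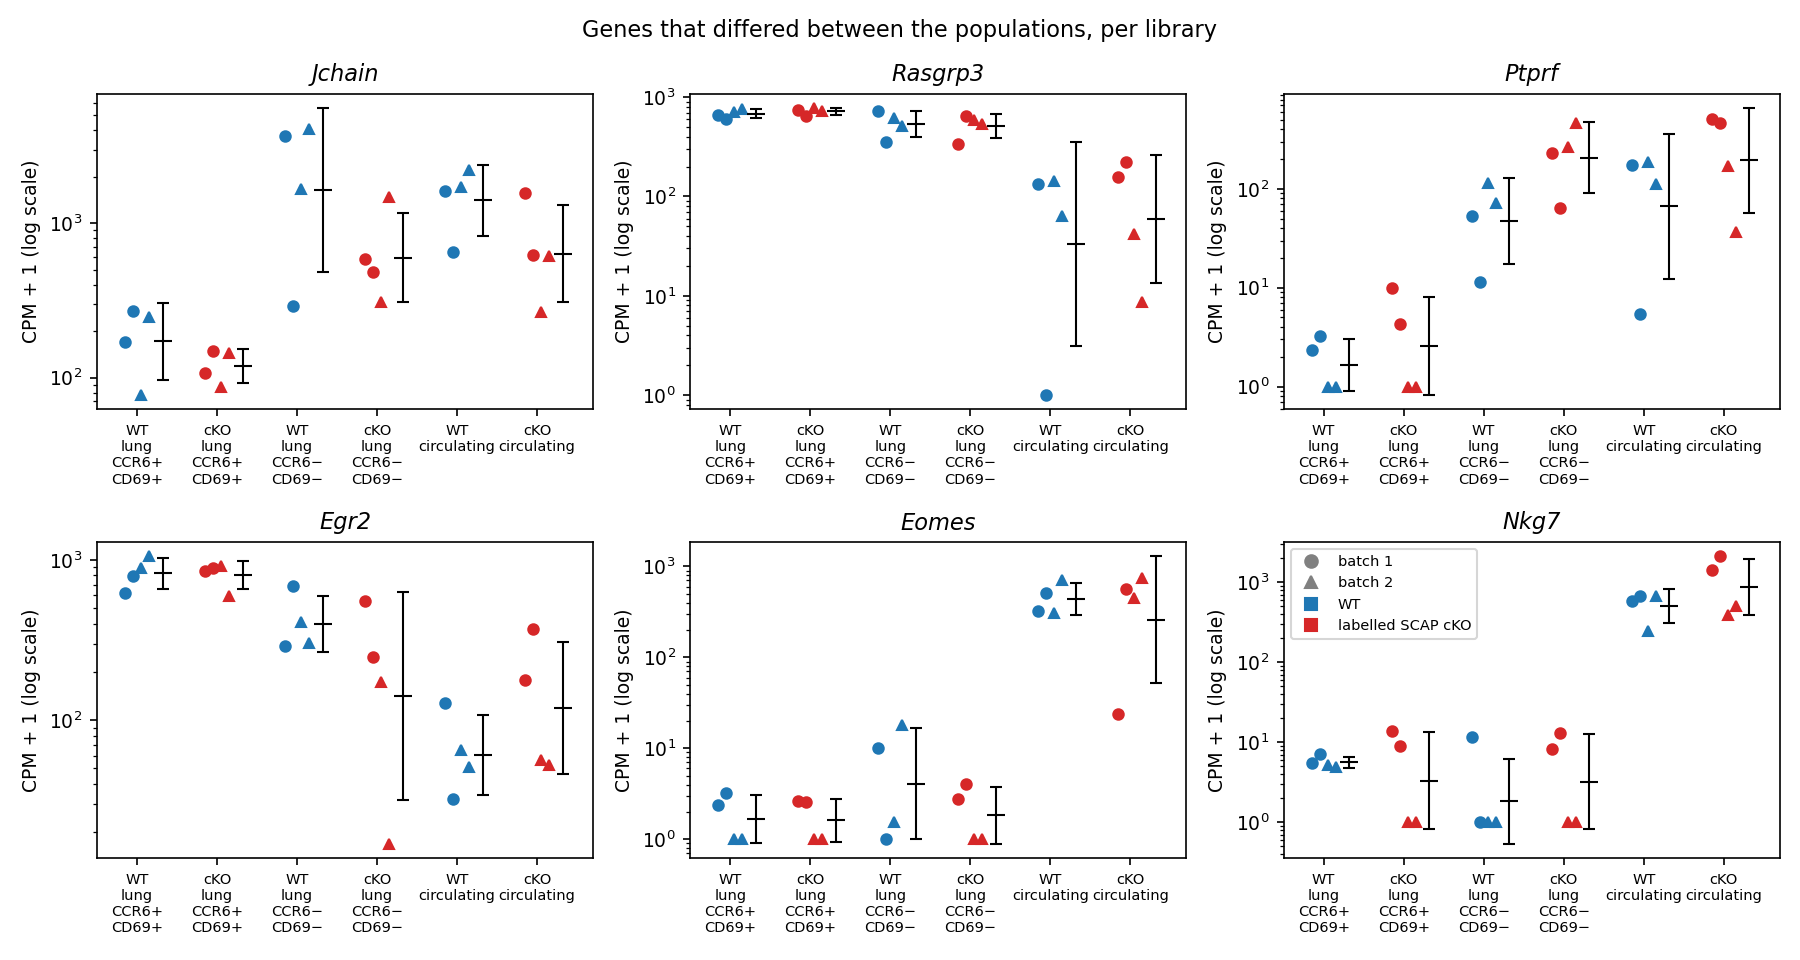
Expression of Jchain, Rasgrp3, Ptprf, Egr2, Eomes and Nkg7 in each library as CPM + 1 on a log scale, by group, with blue for WT, red for labelled SCAP cKO, circles for batch 1 and triangles for batch 2; bars give the mean ± SD of 4 libraries on the log10 scale. In WT, Eomes averaged 464 ± 192 CPM in circulating and 0.898 ± 1.09 CPM in lung CCR6+CD69+ libraries.

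The largest falls in lung CCR6+CD69+ included genes of natural killer cells. Eomes, a T-box factor of natural killer and CD8 T cells, averaged 464 ± 192 CPM in circulating libraries and 0.898 ± 1.09 CPM in lung CCR6+CD69+ (log2 fold change -9.15 ± 1.39, adjusted p 2.42e-05). The killer cell lectin-like receptor genes Klra1 (-9.19 ± 1.91) and Klra4 (-8.76 ± 1.62) fell with it, and Klra7 had 3 counts over the 4 lung libraries against 756 over the 4 circulating ones. Kcnip3 (1 count against 450) and Sytl2 (2 against 425) fell too, as did Ldlrad3 (-8.75 ± 2.09) and Serpinb9b (-8.74 ± 2.18). The T cell and NK cell list was lower in 13 of 13 members (median -4.19, camera adjusted p 2.14e-14), and this call held with an estimated correlation (adjusted p = 0.00404). Of its members 4 fell over all genes and 8 adjusted over the list alone, among them Nkg7, a cytotoxic granule protein (543 ± 205 CPM in circulating against 4.66 ± 1.00 CPM), Ncr1 (-7.22 ± 1.49), Klrb1c (-8.04 ± 1.79) and Cd4 (-4.71 ± 1.07).

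Other lists moved with these markers, and whether RNA of other cells gave part of their falls was not tested. The recirculation and egress list was lower in 10 of 12 members (adjusted p 8.96e-04; adjusted p = 0.0818 with an estimated correlation), with 1 fallen over all genes and 1 adjusted over the list alone. The proliferation list was lower in 16 of 17 (median -1.45, adjusted p 0.0124; adjusted p = 0.496 with an estimated correlation), with Mcm7, a replication helicase subunit, at -2.46 ± 1.14, Ube2c at -2.79 and 0 passing adjusted over the list alone. Plasma cell genes were lower in 6 of 9 (adjusted p 0.0440; adjusted p = 0.213 with an estimated correlation), where Jchain fell, and 1 passed adjusted over the list alone. Unfolded protein response genes were lower in 10 of 12 (adjusted p 0.0107; adjusted p = 0.507 with an estimated correlation), with 0 past the threshold and 1 adjusted over the list alone. Macrophage and monocyte markers were lower in 13 of 17 (adjusted p 9.87e-04; adjusted p = 0.548 with an estimated correlation), with Ccr2, a chemokine receptor of monocytes, at -6.18 ± 1.12 past the threshold. In batch 2 alone that list changed direction and was not called (camera adjusted p 0.811). Dendritic cell markers were lower in 5 of 8 (adjusted p 0.00721; adjusted p = 0.113 with an estimated correlation), where Clec10a (-6.64 ± 1.48) and Ccr9 (-6.77 ± 1.62) fell, and 3 fell and 2 rose adjusted over the list alone. B cell identity genes were not called as a list (adjusted p 0.819), with Ms4a1, which encodes CD20, at 1.29 ± 0.42, and neither was tissue residency (adjusted p 0.912; 2 higher adjusted over the list alone) or fatty acid synthesis (adjusted p 0.0564). Hmgcs1 (-0.35 ± 0.89), Insig1 (-1.01 ± 0.81) and Scd2 (-1.11 ± 0.64) did not pass.

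By edgeR, 80 of 6779 genes passed (11 higher and 69 lower), with 788 at an unadjusted p under 0.05. DESeq2 called 284 (121 higher and 163 lower) and limma voom 285 (95 higher and 190 lower). The edgeR count was 141 without the 2 libraries under 500000 counts and 83 without the 2 led by Chil3. It was 34 in batch 1 alone and 3 in batch 2 alone, and 46 without a batch term. Leaving out WT lung CCR6+CD69+ replicate 1 gave 49 genes and leaving out replicate 4 gave 42.

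Lung CCR6-CD69- and circulating memory B cells of WT mice were compared to see what sets the lung cells without these surface markers apart from circulating cells. Egr2 rose in lung CCR6-CD69- (422 ± 187 CPM against 67.9 ± 41.4 CPM, SD, n = 4; edgeR log2 fold change 2.62 ± 0.62, adjusted p 0.0490), as did Tbc1d9 (5.07 ± 1.09, adjusted p 0.0202). Natural killer cell genes fell: Nkg7 from 543 ± 205 CPM in circulating to 2.63 ± 5.25 CPM (log2 fold change -8.57 ± 1.13, adjusted p 5.83e-06), and Ncr1, an activating receptor of natural killer cells (-6.54 ± 1.47, adjusted p 0.0306). Klra4 (-8.51 ± 1.63), Klra7 (-8.14 ± 1.91), Klre1 (-7.74 ± 1.61), the chemokine Xcl1 (-8.22 ± 1.79) and Tnfrsf9, which encodes the costimulatory receptor 4-1BB (-7.45 ± 1.76), also fell, and Klra1 had 1 count over the 4 lung libraries against 711 over the 4 circulating ones. The T cell and NK cell list was lower in 11 of 13 members (median -2.39, camera adjusted p 2.22e-10), a call that held with an estimated correlation (adjusted p = 0.0198). Of its members 2 fell over all genes and 3 adjusted over the list alone. Whether RNA of other cells in the circulating libraries gave part of the rises of Egr2 and Tbc1d9 was not tested. The proliferation list was lower in 14 of 17 (median -1.04, adjusted p 0.0106; adjusted p = 0.544 with an estimated correlation), with Mcm6 at -1.23 ± 0.86, Cdc20 at -2.93 ± 2.14 and 0 passing adjusted over the list alone. By edgeR, 12 of 6779 genes passed (2 higher and 10 lower), with 585 at an unadjusted p under 0.05. The count was 21 without the 2 libraries under 500000 counts and 1 (Nkg7) without the 2 led by Chil3. It was 3 in batch 1 alone, 0 in batch 2 alone and 0 without a batch term. With both batches DESeq2 called 130 (81 higher and 49 lower), limma voom 38 (6 higher and 32 lower) and edgeR with no filter 32 (12 higher and 20 lower). Leaving out WT lung CCR6-CD69- replicates 1, 2, 3 or 4 gave 2, 1, 3 and 2 genes, and leaving out WT circulating replicates 3 or 4 gave 7 and 2.

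The genotype comparison in lung CCR6+CD69+ cells asked what loss of SCAP does to the transcripts of the lung-resident population. The SREBP targets Hmgcs1, an enzyme of the mevalonate pathway (log2 fold change cKO against WT 0.05 ± 0.88), Insig1, which retains SCAP in the endoplasmic reticulum (-1.20 ± 0.82), and Scd2, a fatty acid desaturase (-0.05 ± 0.63), did not pass (n = 4 per group). Sqle, Idi1 and Fasn were not analysed here. Cholesterol synthesis genes were lower in 10 of 12 tested members (median -0.52), with Mvk, mevalonate kinase, at -2.75 ± 1.74 and Mvd at -2.34 ± 1.64, and 0 passed adjusted over the list alone. Fatty acid synthesis and desaturation genes were lower in 11 of 15 (median -0.41), with the elongase Elovl6 at -2.69 ± 1.55 and Acaca, acetyl-CoA carboxylase, at -2.03 ± 1.20, and 0 passed adjusted over the list alone. Neither list passed in camera (adjusted p 0.0778 for cholesterol and 0.0778 for fatty acid synthesis; adjusted p = 0.740 and 0.740 with an estimated correlation), nor did sterol uptake and SREBP control (adjusted p 0.619).

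As scores per library, cholesterol synthesis averaged 5.44 ± 0.30 log2 CPM in WT and 4.55 ± 0.24 in cKO lung CCR6+CD69+ libraries (SD, n = 4), a difference of -0.90 with all 4 cKO libraries below all 4 WT libraries. Two-sided exact permutation gave p = 0.0286, the smallest that 4 against 4 allows, and 0.129 after adjustment over 9 list and population tests. Within batches the difference was -0.95 in batch 1 and -0.84 in batch 2. Fatty acid synthesis scores were 5.04 ± 0.12 in WT and 4.04 ± 0.44 in cKO, a difference of -0.996 (exact p = 0.0286, adjusted 0.129), again with the libraries apart, and -0.68 and -1.31 within the batches. The sterol uptake score differed by -0.50 (exact p = 0.371). By edgeR, 0 of 6779 genes passed, with 155 at an unadjusted p under 0.05, while limma voom called 0 and DESeq2 called 5 as lower. Named after their values were seen, these were Car2 (log2 fold change -5.35), Rpl29 (-4.11), Exosc6 (-23.4), Shcbp1l (-19.5) and Trim29 (-20.3). Falls as large as those of Exosc6, Shcbp1l and Trim29 cannot be measured at these depths. A total of 0 genes passed without the 2 libraries under 500000 counts and 0 without the 2 led by Chil3, and 1 (Rn18s-rs5, higher in cKO) in batch 1 alone. In the simulated data, with changes only among the more highly expressed genes, 12% of genes changed 4-fold were called at this size and 72% of genes changed 16-fold.

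**Figure D3:**
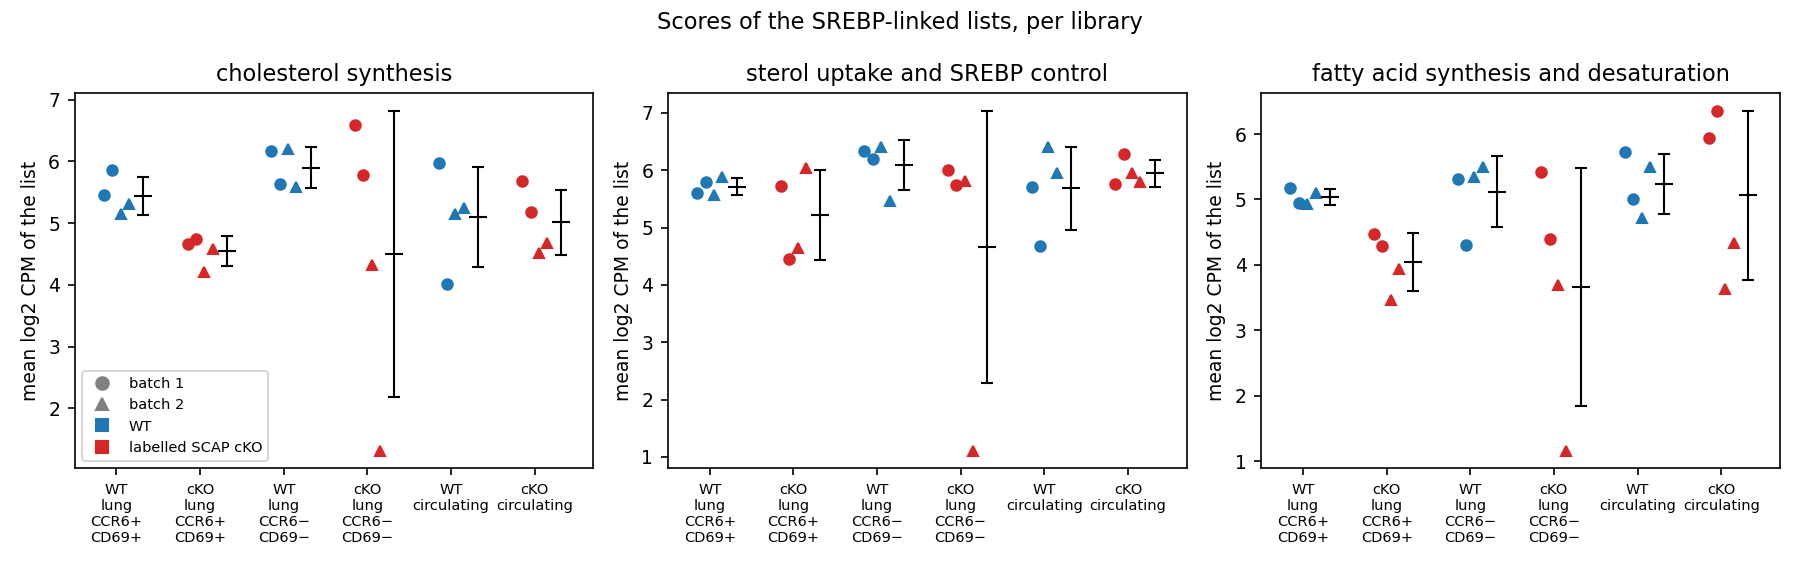
Mean log2 CPM of the tested members of 3 SREBP-linked lists in each library, by group, with blue for WT, red for labelled SCAP cKO, circles for batch 1 and triangles for batch 2; bars give the mean ± SD of 4 libraries. In lung CCR6+CD69+ the cKO libraries differed from the WT libraries by -0.90 for cholesterol synthesis; the lowest cKO lung CCR6-CD69- point is replicate 4, with 129025 counts.

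In lung CCR6-CD69- cells the same question found the SREBP targets Hmgcs1 at -0.60 ± 0.89 (log2 fold change cKO against WT, SE, n = 4), Insig1 at -1.42 ± 0.82 and Scd2 at -0.19 ± 0.63, none past the threshold. The cytosolic ribosomal protein list was called as higher in cKO by camera (adjusted p 0.00958; adjusted p = 0.910 with an estimated correlation), although only 12 of 21 members were higher and the median was 0.02. Rpl27, of the large subunit, was at 1.20 ± 0.44 and Rps15, of the small subunit, at 1.02 ± 0.37; 0 passed over all genes and 0 adjusted over the list alone. Ribosomal protein genes took fewer counts in batch 2 than in batch 1. Cholesterol synthesis scores were 5.90 ± 0.33 in WT and 4.50 ± 2.33 in cKO libraries (exact permutation p = 0.343), with differences of 0.28 in batch 1 and -3.08 in batch 2, the batch that holds cKO replicate 4. Macrophage and monocyte markers took 6.09% of counts in cKO replicate 1 and at most 0.494% in the other 3 cKO libraries. By edgeR, 0 of 6779 genes passed, with 496 at an unadjusted p under 0.05, while DESeq2 called 90 and limma voom 0. Leaving out cKO replicate 1 gave 2 genes (Elavl2 and Rpl38) and leaving out replicate 2 gave 1 (Elavl2), named after their values were seen. The count was 0 without the 2 libraries under 500000 counts and 0 without the 2 led by Chil3.

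In circulating cells Hmgcs1 was at 1.29 ± 0.90 (log2 fold change cKO against WT, SE, n = 4), Insig1 at -0.60 ± 0.81 and Scd2 at 0.84 ± 0.63, none past the threshold. The NF-kB response list was higher in cKO in 13 of 13 tested members (median 1.55, camera adjusted p 0.0381; adjusted p = 0.958 with an estimated correlation). The chemokine Ccl22 was at 5.24 ± 1.65, Bcl2a1b at 4.31 ± 1.14, the adaptor Traf1 at 2.29 ± 0.72 and Nfkbie, an inhibitor of NF-kB, at 1.96 ± 0.64; 0 passed over all genes and 4 rose adjusted over the list alone. T cell and NK cell markers were not called between these genotypes (adjusted p 0.902), with Nkg7 at 1105 ± 809.8 CPM in cKO and 543 ± 205 CPM in WT libraries. Cholesterol synthesis scores differed by -0.08 (exact permutation p = 0.857), with 0.43 in batch 1 and -0.60 in batch 2. By edgeR, 0 of 6779 genes passed, with 693 at an unadjusted p under 0.05, while DESeq2 called 233 and limma voom 0. The count was 0 without the 2 libraries under 500000 counts and 0 without the 2 led by Chil3, and leaving out WT circulating replicate 1 gave 1 gene (Trim5, higher in cKO).

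Whether the genotype effect differed between populations was tested directly. For lung CCR6+CD69+ minus lung CCR6-CD69-, Hmgcs1 had a difference of effects of 0.65 ± 1.25 (log2, SE, n = 4 per group), Insig1 0.23 ± 1.13 and Scd2 0.14 ± 0.88. For lung CCR6+CD69+ minus circulating the differences were -1.24 ± 1.26, -0.59 ± 1.13 and -0.89 ± 0.89 for Hmgcs1, Insig1 and Scd2. None passed, and camera called no list in either test. By edgeR, 0 of 6779 genes passed in each, with 235 and 367 at an unadjusted p under 0.05, while DESeq2 called 6 and 30 and limma voom 0 in each. The counts were 0 and 0 without the 2 libraries under 500000 counts, and 0 and 0 without the 2 led by Chil3.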

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

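Every library was compared with the other 3 of its group by a gap test set before the data were examined, so no test here was chosen after its result was seen, and no biological explanation was tested. Of 216 group and measure combinations 15 had a library standing far from the other 3, where chance gives about 10.8. WT circulating replicate 2 held 356782 counts, against 2262715 to 2466421 in the others. Immunoglobulin genes took 0.138% of counts in WT circulating replicate 4 (others 0.0276 to 0.0286%) and 0.0643% in cKO circulating replicate 1 (others 0.0220 to 0.0267%). These shares cover the 73 immunoglobulin rows analysed, which leave out Ighg1, so they do not measure total immunoglobulin.

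The remaining 12 were list scores in mean log2 CPM. cKO lung CCR6-CD69- replicate 4, with 129025 counts, stood low for sterol uptake and SREBP control (1.10, others 5.75 to 6.00), NF-kB response (3.32, others 7.03 to 7.71), unfolded protein response (4.38, others 7.76 to 8.32) and T cell and NK cell markers (0.50, others 2.91 to 3.38). WT circulating replicate 1 stood high for NF-kB response (6.70, others 5.46 to 5.61), MHC class II presentation (10.52, others 8.96 to 9.16) and lung epithelium markers (6.30, others 3.02 to 3.52), and low for T cell and NK cell markers (4.13, others 5.83 to 5.91). WT lung CCR6-CD69- replicate 1 stood low for tissue residency (6.14, others 7.35 to 7.54) and immediate early genes (8.31, others 8.91 to 9.01). Fatty acid synthesis was low in WT lung CCR6-CD69- replicate 2 (4.31, others 5.32 to 5.50), and apoptosis regulators were high in WT lung CCR6+CD69+ replicate 2 (6.85, others 6.31 to 6.37).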

How the results depend on the processing

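The alternatives without the 2 libraries under 500000 counts, without the 2 led by Chil3, and with limma voom were chosen after the data were seen; the others were planned, and none was left unrun. The cause of each change below was not tested. WT lung CCR6+CD69+ against lung CCR6-CD69- (20 genes, 0 higher) gave 54 with DESeq2 (3 higher), 38 with no filter (2 higher), 6 without a batch term, 6 in batch 1 alone, 2 in batch 2 alone, 81 with only the groups compared (9 higher), 155 with limma voom (26 higher) and 13 with the replicate number as a block. Leaving out single libraries gave 0 to 20: 0, 6, 4 and 1 without CCR6+CD69+ replicates 1 to 4, and 9 without CCR6-CD69- replicate 1 or 3. WT lung CCR6+CD69+ against circulating (80 genes, 11 higher and 69 lower) gave 284 with DESeq2 (121 higher, 163 lower), 46 without a batch term, 34 in batch 1, 3 in batch 2, 141 without the shallow libraries and 285 with voom (95 higher, 190 lower). Single libraries left out gave 42 to 79, with 49 and 42 without CCR6+CD69+ replicates 1 and 4. WT lung CCR6-CD69- against circulating (12 genes, 2 higher) gave 130 with DESeq2 (81 higher, 49 lower), 32 with no filter, 0 without a batch term, 3 in batch 1, 0 in batch 2, 22 with only the groups compared, 21 without the shallow libraries, 1 without the Chil3 libraries and 38 with voom. Single libraries left out gave 1 to 12: 2, 1, 3 and 2 without CCR6-CD69- replicates 1 to 4, and 7 and 2 without circulating replicates 3 and 4.

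The genotype comparisons, each with 0 genes in edgeR (155 in lung CCR6+CD69+, 496 in CCR6-CD69- and 693 in circulating at an unadjusted p under 0.05), gave more in some settings. In lung CCR6+CD69+ DESeq2 called 5 and batch 1 alone 1, with 0 to 0 over single libraries left out. In lung CCR6-CD69- DESeq2 called 90, no filter 11 and only the groups compared 3 (Ighv1-64, Paqr5 and Rbbp9), with 0 to 2 over single libraries left out (2 without cKO replicate 1, 1 without replicate 2). In circulating cells DESeq2 called 233 and batch 1 alone 2 (Lime1 and Prkcd), with 0 to 1 over single libraries left out (1 without WT replicate 1). The difference of effects between the lung populations (235 at an unadjusted p under 0.05) gave 6 with DESeq2 and 3 with no filter (Exosc6, Paqr5 and Rps21), and that between lung CCR6+CD69+ and circulating (367) gave 30 with DESeq2 and 1 (Lime1) in batch 1 alone, each with 0 to 0 over single libraries left out. Voom called 0 in all 5.

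Of 248 list tests 19 were called, and 2 with an estimated correlation, 2 with fry, 7 in batch 1 and 12 in batch 2; single libraries left out gave 17 to 23. Of 4714 comparisons of a named gene with an alternative, 3866 kept direction and side of the threshold, 715 kept direction and lost the call, 76 gained it and 54 changed sign without a call either way. Elavl2, called at -11.03 between the cKO lung populations, lost the call and changed sign in 3: 0.65 in batch 1 (adjusted p 0.986), 0.60 without the shallow libraries (0.969) and 0.79 without cKO lung CCR6-CD69- replicate 4 (0.971; -12.2 to 0.79 over single libraries left out). No value came from the stricter filter for Lef1, from batch 1 alone for Tnfrsf9 and Sytl2, or from batch 2 alone for Elavl2 and Batf3, which were not among the genes tested there. Of 908 such list comparisons 783 were the same, 91 lost the call, 2 gained it, 30 changed sign without a call and 2 reversed: the macrophage list between WT lung CCR6+CD69+ and circulating in batch 2 (adjusted p 0.811) and the ribosomal protein list in lung CCR6-CD69- with fry (adjusted p 0.853). Relative log expression factors moved the median log2 fold change of all genes in the difference of effects between lung populations from 0.29 to 0.14. Depth set the floor of 3 counts at 23.3 CPM in the smallest library; how much of the median SE of 1.25 over all genes in the first comparison comes from depth was not tested.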

Other observations

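The tests on the cKO populations, the averaged genotype effect, the counts of other splits apart from that of the averaged effect, the natural killer and plasmacytoid dendritic cell tests, the SREBP score test and the batch and ribosomal protein tests of Rpl29 were chosen after the results, or values behind them, were seen. In cKO mice, antigen presentation genes differed between lung CCR6+CD69+ and circulating libraries. H2-DMb2, a subunit of the peptide exchange factor H2-DM, rose (1572 ± 403 against 299.9 ± 179 CPM, SD, n = 4; edgeR log2 fold change 2.48 ± 0.47, adjusted p 5.60e-04), as did H2-Eb1 (1.49 ± 0.33) and the invariant chain Cd74 (1.06 ± 0.27). The MHC class II list was higher in 7 of 8 members (camera adjusted p 0.01002; adjusted p = 0.510 with an estimated correlation), 3 past the threshold and 4 adjusted over the list alone. Egr2 (2.58 ± 0.63) and Rasgrp3 (2.85 ± 0.73) rose as well. The B cell gene Ms4a1 averaged 1550 ± 87.8 CPM in cKO lung CCR6+CD69+ and 758 ± 347 CPM in cKO circulating libraries. Nkg7 averaged 5.18 ± 6.29 and 1105 ± 809.8 CPM in the same groups. Whether RNA of other cells in the circulating libraries gives part of these rises was not tested. Fatty acid synthesis genes were lower in 12 of 15 (adjusted p 0.01002; adjusted p = 0.477 with an estimated correlation), 1 past the threshold and 3 adjusted over the list alone. T cell and NK cell markers were lower in 11 of 13, a call that held with an estimated correlation (adjusted p = 0.0120). Camera at the preset correlation also called the plasma cell, macrophage and monocyte, and dendritic cell lists. Their median log2 fold changes were -1.72, -1.01 and -1.55. On the plasmacytoid dendritic cell list written after the values were seen, 22 of 22 tested genes were lower and 13 passed. Il12rb2, a chain of the interleukin 12 receptor, had 0 counts over the 4 lung libraries and was at least 652-fold lower there than in circulating libraries, and Cd27 at least 355-fold, each against a floor of 3 counts over the group. By edgeR 104 genes passed (5 higher and 99 lower), 52 in batch 1 alone, 15 in batch 2 alone, 69 with only the groups compared and 80 without a batch term, while DESeq2 called 488 (197 higher and 291 lower) and limma voom 144. The edgeR count was 213 (42 higher) without the 2 libraries under 500000 counts and 110 without the 2 led by Chil3. Leaving out cKO lung CCR6+CD69+ replicates 1, 2 or 3 gave 67, 64 and 64.

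Between the cKO lung populations, Ccr9, a chemokine receptor of gut-homing lymphocytes and plasmacytoid dendritic cells, averaged 4.76 ± 5.65 CPM in CCR6+CD69+ and 1013 ± 1203 CPM in CCR6-CD69- libraries (SD, n = 4; edgeR log2 fold change -8.55 ± 1.76, adjusted p 0.0331). The highest Ccr9 value, 2799 CPM, was in CCR6-CD69- replicate 4, the library with the fewest counts, and raised that mean. Pooled over the counts of the CCR6-CD69- group Ccr9 was at 394 CPM. Ptprf (-6.89 ± 1.40), Tbc1d8 (-7.20 ± 1.29), Fmnl2 (-7.57 ± 1.46) and the fatty acid desaturase Fads2 (-7.26 ± 1.66) fell too. The first 3 of these had also fallen in WT. Macrophage markers were lower in 14 of 17 (adjusted p 4.49e-05; adjusted p = 0.896 with an estimated correlation). By edgeR 31 genes passed (0 higher), while DESeq2 called 347 (72 higher and 275 lower) and limma voom 41. The edgeR count was 55 with relative log expression factors, 84 with no filter, 13 without a batch term, 8 in batch 1 alone, 8 in batch 2 alone (3 higher), 8 with only the groups compared and 20 with the replicate number as a block. It was 38 without the 2 libraries under 500000 counts and 35 without the 2 led by Chil3, and 15, 12, 13 and 14 without CCR6+CD69+ replicates 1 to 4. Between cKO lung CCR6-CD69- and circulating cells Nkg7 was at -8.11 ± 1.14 and Eomes at -8.51 ± 1.42, among 21 genes (2 higher and 19 lower) in edgeR. Camera at the preset correlation called the MHC class II list here too (median log2 fold change 0.57), and the T cell and NK cell list (median -2.30). DESeq2 called 520 (294 higher) and limma voom 12. The edgeR count was 51 (29 higher and 22 lower) with relative log expression factors, 101 with no filter, 9 without a batch term, 1 in batch 1 alone, 11 in batch 2 alone, 4 with only the groups compared, 10 without the 2 libraries under 500000 counts, 31 without the 2 led by Chil3 and 13 without circulating replicate 1.

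The batches differed by transcript length. Over 4 bins of tested genes by annotated transcript length, from the shortest (median 1254 bases) to the longest, the median log2 fold change of batch 2 against batch 1 was -1.38, -0.50, -0.15 and 0.16. In edgeR 334, 66, 30 and 13 genes in these bins were lower in batch 2.

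The natural killer and dendritic cell transcripts that were low in WT lung CCR6+CD69+ against circulating libraries may come from such cells, or their RNA, which a sort for memory B cells is meant to remove. On marker lists written after the called genes and the values of every library were known, 31 of 31 natural killer genes were lower (20 called; median log2 fold change -6.79, and -6.91 with the gene without counts at its bound), as were 21 of 22 plasmacytoid dendritic genes (11 called) and 10 of 11 T cell genes (1 called), each list sharing 1 gene with a B cell list, while Ms4a1 was at 1303 ± 97.4 CPM in lung CCR6+CD69+ and 531 ± 218 CPM in circulating, and Nkg7 at 543 ± 205 CPM in circulating. Sequencing depth is argued against: with WT libraries thinned to 356782 counts the natural killer score still differed by 3.29 log2 (4.84 unthinned), all 4 circulating libraries above all 4 lung ones. The planned T cell and NK cell list was lower in 11 of 13 members in cKO lung CCR6+CD69+ against cKO circulating libraries (camera in limma, adjusted p = 0.0120 with an estimated correlation), in line with natural killer cells or their RNA, though memory B cells that carry these transcripts would give the same and stay open. Plasmacytoid dendritic cells cannot be told apart from expression in the B cells: the list was written with the cKO values known, so the exact permutation p of 0.0121 for its 11 members not called in WT (median -1.33 in cKO) decides nothing.

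In lung CCR6+CD69+ the synthesis scores were lower in all 4 cKO than in all 4 WT libraries. That is the direction that loss of SREBP activity could give. Lists outside sterol and lipid synthesis fell there too: IL-4 and STAT6 response averaged 4.32 ± 0.36 in WT and 3.21 ± 0.44 in cKO (SD). Germinal centre averaged 5.14 ± 0.14 and 4.46 ± 0.34. Other scores were higher in cKO, MHC class II presentation among them (10.5 ± 0.36 and 10.8 ± 0.47). Such lists had no score test, so the falls cannot be called particular to SREBP targets. Depth is argued against, since the cholesterol synthesis difference was -0.90 with the 8 libraries thinned to 2081557 counts. A shift of all genes of like expression is argued against only as the source of the whole difference. Of 10000 random lists matched on mean expression 0.27% had a lower difference, and 0.16% for fatty acid synthesis. The central range of these lists ran from -0.71 to 0.16 for cholesterol and from -0.78 to 0.06 for fatty acid synthesis. Genes of like expression thus tended lower in cKO as well. Random genes were drawn independently, so this range may be too narrow for lists whose genes move together. Lower SREBP targets after SCAP deletion cannot be told apart from no effect, because the smallest adjusted exact permutation p over 9 tests was 0.129 and exact tests of 4 against 4 libraries stop at 0.0286. Hmgcs1 (0.05 ± 0.88) and Scap itself (0.08 ± 0.93) did not pass in edgeR.

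Rpl29, a ribosomal protein gene, was lower in cKO over the 3 populations together (edgeR log2 fold change -3.77 ± 0.60, adjusted p 2.08e-04), at 131 to 884 CPM in the 12 WT libraries and 0 to 155 CPM in the 12 labelled SCAP cKO. A difference between batches alone could not give this, since every group has 2 libraries in each batch. In edgeR the fall was -2.45 ± 0.49 (adjusted p 0.0271) in batch 1 and -5.80 ± 1.13 (adjusted p 0.175, not passing) in batch 2. These tests on Rpl29 take all libraries of a genotype as separate samples. The labels do not say whether the 3 populations came from the same animals, which would leave fewer. A shift of all ribosomal protein genes is argued against by the median of 0.18 (median absolute deviation 0.304) over the 53 others. Rpl29 and Scap lie on the same chromosome with 25 tested genes between them, but the 100 tested genes nearest Scap, Rpl29 included, had a larger median genotype statistic than only 0.832% of 4685 such windows, so the test gave no support for a strain region that shifts many genes there. A variant carried along with the floxed allele that lowers Rpl29 alone may still be the source and cannot be told apart from an effect of SCAP loss, since every cKO library would carry both. The adjusted p ran from 7.62e-11 with DESeq2 to 0.369 without a batch term (log2 fold change -2.74), was 0.189 with limma voom, and stayed at or below 0.00299 with any single library left out (-4.03 to -3.50).

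In all, 8 genes passed in the genotype effect averaged over populations in edgeR (1 higher), with 502 at an unadjusted p under 0.05, while DESeq2 called 77 (18 higher and 59 lower) and limma voom 0. The edgeR count was 28 with no filter, 0 without a batch term, 2 in batch 1 alone, 1 in batch 2 alone and 1 with the replicate number as a block. It was 1 without the 2 libraries under 500000 counts, 1 without the 2 led by Chil3, and 1 or 2 without any single library other than WT lung CCR6+CD69+ replicates 2 and 3, WT lung CCR6-CD69- replicate 1 and WT circulating replicates 1 and 4 (8, 8, 6, 8 and 7).

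Other splits of the same libraries were counted for each comparison. For the averaged genotype effect, 100 splits were drawn within population and batch, and only the real split gave as many (1 of 100, 8 genes, highest other 2). Libraries were moved separately in each population. Chance is therefore excluded only if the populations came from separate animals, which the labels do not say. For pairs of populations, only 18 of the 35 splits keep 2 libraries of each batch per group, too few for a share under 0.05. Over all 35, which also move libraries between batches, the real split alone (1 of 35) gave as many for WT lung CCR6+CD69+ against lung CCR6-CD69- (20 genes, highest other 1), WT lung CCR6+CD69+ against circulating (80, highest other 1) and WT lung CCR6-CD69- against circulating (12, highest other 2). The real split was also alone for cKO lung CCR6+CD69+ against lung CCR6-CD69- (31, highest other 11) and against circulating (104, highest other 5). That share of 35 does not exclude chance for these 5. The unbalanced splits mix group with batch, and the 18 balanced ones are too few. Among the 18 the highest others were 1, 0, 0, 11 and 0, each below the real count. For cKO lung CCR6-CD69- against circulating, 2 of 35 splits gave as many as the real 21, so chance is not excluded: the split that follows the batch gave 174, within batches the real count was 1 and 11, and the highest other among the balanced splits was 1.

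For the genotype comparisons and the differences of effects the real edgeR count was 0, so every split (35 of 35) gave as many and the splits decide nothing. The highest others were 2 in lung CCR6+CD69+, 2 in lung CCR6-CD69-, 20 in circulating cells, and 2 and 1 for the differences of effects; all but the 20 came from the split that follows the batch. The split with 20 genes joined WT circulating replicates 1 and 3 with cKO circulating replicates 1 and 2, so 3 of its 4 libraries are of batch 1; the split that follows the batch gave 4, and the balanced splits at most 0. As the highest of 34 others with a median of 0, it may point to a structure among those libraries, which was not tested. Unadjusted p was under 0.05 for 155, 496, 693, 235 and 367 genes in these 5 comparisons, and DESeq2 called 5, 90, 233, 6 and 30, limma voom 0 in each.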
